A study of Mus musculus with 4 samples.

How the data were processed

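RNA was measured on 4 Affymetrix mouse expression arrays. Per the labels' protocols, human embryonic kidney-derived 293EBNA cells were grown as flank tumours in mice to a volume of 2000 mm3. The cells carried the empty expression vector Apex or the same vector with VEGFD, the gene of vascular endothelial growth factor D. Per the labels' protocols, a blue dye injected into the tumour marked the collecting lymphatic vessels that drained it, the vessels were dissected out, and endothelial cells were taken from the cell suspension by magnetic sorting. The extraction protocol speaks of lymph node endothelial cells where the other labels speak of collecting lymphatic ones, and the groups below follow the latter. Total RNA was labelled with biotin by the one-cycle Affymetrix procedure, per the labels' protocols. The titles name 2 biological replicates in each group, and the sources used here do not say whether each was 1 mouse or a pool.

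The deposited values were linear intensity, 1 signal per probe set, from 0.0265 to 15170. The algorithm and software behind the probe set signals are not given in the sources used here. As found from the deposited intensity values, each array had the same mean of 150 after trimming 2% of the probe sets at each end, and no other scaling between arrays was found. No detection calls were used, so a low signal has no stated limit against background. The median signal was 27.0 and 30.4 in Apex replicates 1 and 2, and 26.3 and 23.8 in VEGFD replicates 1 and 2. The precision of every comparison is limited by the number of arrays, 2 in each group.

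The arrays held 45101 probe sets, of which 64 were controls. The platform annotation paired 34945 probe sets with 1 gene symbol and 932 with several, and 9160 were unnamed here. Of the single-gene probe sets, 34741 were found by gene ID in the GRCm38.p6 reference gene table, and no symbol needed an update. Probe sets with several genes named no gene. The genome build behind the array design is not given in the sources used here, so no positions are printed.

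Values were used as log2(signal + 16), so the fold changes of dim genes are understated. Each gene was represented by its probe set with the highest mean over the 4 arrays, which left 18193 genes. Genes were kept when that mean was at or above the median of all non-control probe sets, 5.37 on the log2 scale or a signal of 25.3. That left 11680 tested genes. VEGFD and Apex arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. An exact permutation test of 2 arrays against 2 has 3 splits and cannot go below p = 0.333. A second count therefore describes, without a test, the genes at least 2-fold apart whose VEGFD values both lay on the same side of both Apex values. The same count was made for the other splits of the arrays.

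Gene lists were fixed before the data were examined, 29 in all, for vessel, prostaglandin and growth factor genes, for cell types that dissected tissue can hold, and for general cell programmes. Lists with at least 5 tested genes were tested with limma's camera, with a correlation between genes of 0.01 and adjustment over the 27 lists tested. The same lists were run with fry, which asks whether a list moves one way on balance, and with an estimated correlation. Camera with an estimated correlation judges lists by the few arrays rather than the many genes, so it could hardly call any list here. On all 4 arrays no list had an adjusted p below 0.919, also where the estimate lay below 0.01. Those adjusted p values therefore do not test whether a call depends on correlation between genes. The rule for named genes was also fixed before the data were examined. It took the 12 higher and 12 lower genes past the threshold with at least a 2-fold change and no overlap, ranked by size. Where fewer passed, the places went to the genes with the smallest unadjusted p among those 2-fold apart without overlap, leaving out predicted genes. It always took 12 genes of the prostaglandin, vascular growth factor and lymphatic systems, of which Ptgs1 was unnamed here. From each list it took up to 4 passing members, or the 2 with the largest change where none passed. Genes named outside this rule were chosen after their values were seen, except the limb-level genes, whose test was written before its result.

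The procedure was tested on simulated data for VEGFD against Apex, with 11680 genes, 20 runs and 200 changed genes in each run. It called 0.50% of genes changed 2-fold, 35.8% of those changed 4-fold, 79.0% of those changed 8-fold and 91.9% of those changed 16-fold, with a mean of 5.15 false calls a run. Of 540 list tests in those runs, with the changed genes drawn at random from all genes, 1 was called. The simulated genes varied independently, so this rate does not carry over to lists whose members vary together. Alternatives covered the scaling between arrays, the filter on dim probe sets, the choice of probe set, the variance model and the replicate number as a block. They also covered the pseudocount, the threshold, the list test and each array left out in turn. With an array left out, 1 group has 1 array, so the p values hold no variation within that group. The block is an added term fitted to the same arrays, so less is left to estimate variation from. Its passes lean more on the variance shared across genes. A floor on low values was planned for log2 data only and did not apply to linear values. Of the named genes, 37 had several probe sets above the filter, and in 5 of these (Htr1b, Ighm, Mbp, Rbmx and Scyl2) the probe sets differed in sign.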

Results

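Gene expression was measured in cells labelled as endothelium sorted from the collecting lymphatic vessels that drained a tumour, with 2 arrays from mice whose tumours carried the empty Apex vector and 2 from mice whose tumours overproduced VEGF-D. VEGF-D is a secreted growth factor that acts on lymphatic and blood vessel endothelium through the receptors encoded by Flt4 and Kdr. The question was how the endothelium of draining collecting lymphatics differs when the tumour makes VEGF-D. Several marker signals went against the endothelial label in 3 of the 4 arrays. Pecam1, Tie1 and Erg exceeded the signal of the filter on dim probe sets, 25.3, in Apex replicate 2 alone. Tie1 and Erg were chosen after their values were seen. The pan-endothelial genes that the rule named were less clear. Emcn also exceeded 25.3 in Apex replicate 1 (48.4) and VEGFD replicate 1 (106), and Egfl7 exceeded it on every array. The lymphatic gene Prox1 was at most 14.6 on any array over its 3 probe sets. Another lymphatic marker, Pdpn, had signals of 963, 1622, 1237 and 1715. Col1a2, a collagen I gene also chosen after its values were seen, had signals of 5555, 6846, 6122 and 6623. The filter kept 10 of 16 pan-endothelial, 10 of 14 lymphatic and 11 of 14 fibroblast markers, against 11680 of all 18193 genes. Such shares say little about cell type. The arrays are therefore named by their labels throughout. After the filter, 11680 genes were compared. All log2 changes are VEGFD minus Apex on the log2(signal + 16) scale with the standard error (SE) of the limma fit, n = 2 and 2, and signals are given in the order Apex replicate 1, Apex replicate 2, VEGFD replicate 1 and VEGFD replicate 2.

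The smallest adjusted p belonged to a gene with less signal in VEGFD arrays. Dpt, which encodes the matrix protein dermatopontin, had signals of 2725, 2407, 204 and 168, a log2 change of -3.68 ± 0.23 (SE) and an adjusted p of 0.110. Col6a1 and Col6a2, which encode chains of collagen VI, had log2 changes of -2.44 ± 0.25 and -3.23 ± 0.33. Among genes with more signal in VEGFD arrays, Hoxc8, a positional transcription factor, had signals of 84.5, 43.8, 516 and 498, a log2 change of 2.75 ± 0.32 and an adjusted p of 0.419. None of these passed the main test. With the replicate number as a block on all 4 arrays, Dpt (adjusted p = 0.0183) and Col6a2 (0.022) passed in limma. The labels do not say whether same-numbered arrays pair. Without VEGFD replicate 1 the log2 changes were -3.80 for Dpt, -2.54 for Col6a1, -2.83 for Col6a2 and 2.73 for Hoxc8. Without VEGFD replicate 2 they were -3.55, -2.34, -3.63 and 2.78 in the same order. Passes named below with a VEGFD array left out hold no variation between VEGFD arrays and are not support for a gene.

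No gene of the 11680 passed an adjusted p of 0.05 in the main limma fit, which had no block, and the smallest adjusted p was that of Dpt. At an unadjusted p under 0.05 there were 666 genes where 584 would arise by chance, 227 of them higher and 439 lower in VEGFD arrays. The same limma count was 717 for the split by replicate number and 112 for the remaining split, so the 666 is no excess tied to the groups. At least 2-fold apart without overlap were 446 genes, 124 higher and 322 lower. With arrays centred on their medians these were 188 higher and 236 lower. Of all tested genes, 38.4% had no overlap between groups, where chance gives 33.3%. Splitting the arrays by replicate number instead gave 486 genes 2-fold apart without overlap, and the remaining split gave 147. The count that passed was 390 without VEGFD replicate 1 (146 higher, 244 lower), 4 without VEGFD replicate 2 (all lower), and 0 without either Apex array, with the lone array assumed to vary like the others. The count 2-fold apart was 949 without Apex replicate 1, 436 without Apex replicate 2, 1329 without VEGFD replicate 1 and 568 without VEGFD replicate 2. No overlap is easier to meet with fewer arrays, so these counts are not comparable with the 446.

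The 12 lower genes named by rank were all short of the threshold on 4 arrays without a block. With the replicate number as a block, Dpt (adjusted p = 0.0183), Ptn (0.022), Col6a2 (0.022) and Gas1 (0.0336) passed in limma. After Dpt, Col6a1 and Col6a2 came Ptn, which encodes the heparin-binding growth factor pleiotrophin, with signals of 238, 528, 0.464 and 7.50. Its VEGFD signals lay below the filter signal, so its log2 change of -4.24 depended on the pseudocount. It was -2.64 with a pseudocount of 64, -2.58 with averaged probe sets, and -0.40 with a pseudocount of 1, where a different probe set was the brightest. Gas1, a growth arrest gene whose product binds hedgehog ligands, had a log2 change of -2.84 ± 0.30, and Cdh13, which encodes T-cadherin, had -2.68 ± 0.37. Cbln2 had -2.65 ± 0.29, Cst6, which encodes the protease inhibitor cystatin E/M, -2.57 ± 0.37, and Angptl7, an angiopoietin-like gene, -2.54 ± 0.37. Serpinb9g had -2.43 ± 0.32, Frmd4b -2.32 ± 0.32 and Dnm1, which encodes the membrane-scission protein dynamin, -2.09 ± 0.26. With averaged probe sets the values were -1.72 for Cdh13, -1.02 for Dnm1 and -0.75 for Frmd4b. The VEGFD signals of Cbln2 also lay below the filter signal, and with a pseudocount of 64 its log2 change was -1.56 and that of Angptl7 -1.69. Without the block the limma adjusted p values of the lower genes ran from 0.110 to 0.519.

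The 12 higher genes named by rank did not pass on 4 arrays, with or without the block. Cxcl14, which encodes a chemokine, had signals of 98.7, 16.6, 514 and 1089 and a log2 change of 3.65 ± 0.68. Fgf18, a fibroblast growth factor gene, had a log2 change of 1.98 ± 0.36. Krt7, a keratin gene, had 1.80 ± 0.27, and Slc2a1, which encodes the glucose transporter GLUT1, had signals of 844, 670, 1878 and 2086 and a log2 change of 1.38 ± 0.23. Slc1a6, a glutamate transporter gene, had 2.03 ± 0.31, Hoxb2, another positional transcription factor gene, 1.72 ± 0.35, Rrp9 1.79 ± 0.35 and Rtbdn 1.44 ± 0.28. Rbmx (2.29 ± 0.42), Htr1b (1.77 ± 0.36) and Scyl2 (1.33 ± 0.25) had other probe sets of the opposite sign, and with averaged probe sets they were at 0.36, 0.80 and 0.49. The Apex signals of Slc1a6, Rbmx and Rtbdn lay below the filter signal, and with a pseudocount of 64 their log2 changes were 1.07, 1.42 and 0.69, while that of Rrp9 was 1.15. With a pseudocount of 1 Slc1a6 was 3.05 and Rtbdn 2.27. The adjusted p values of the higher genes ran from 0.419 to 0.722.

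**Figure D1:**
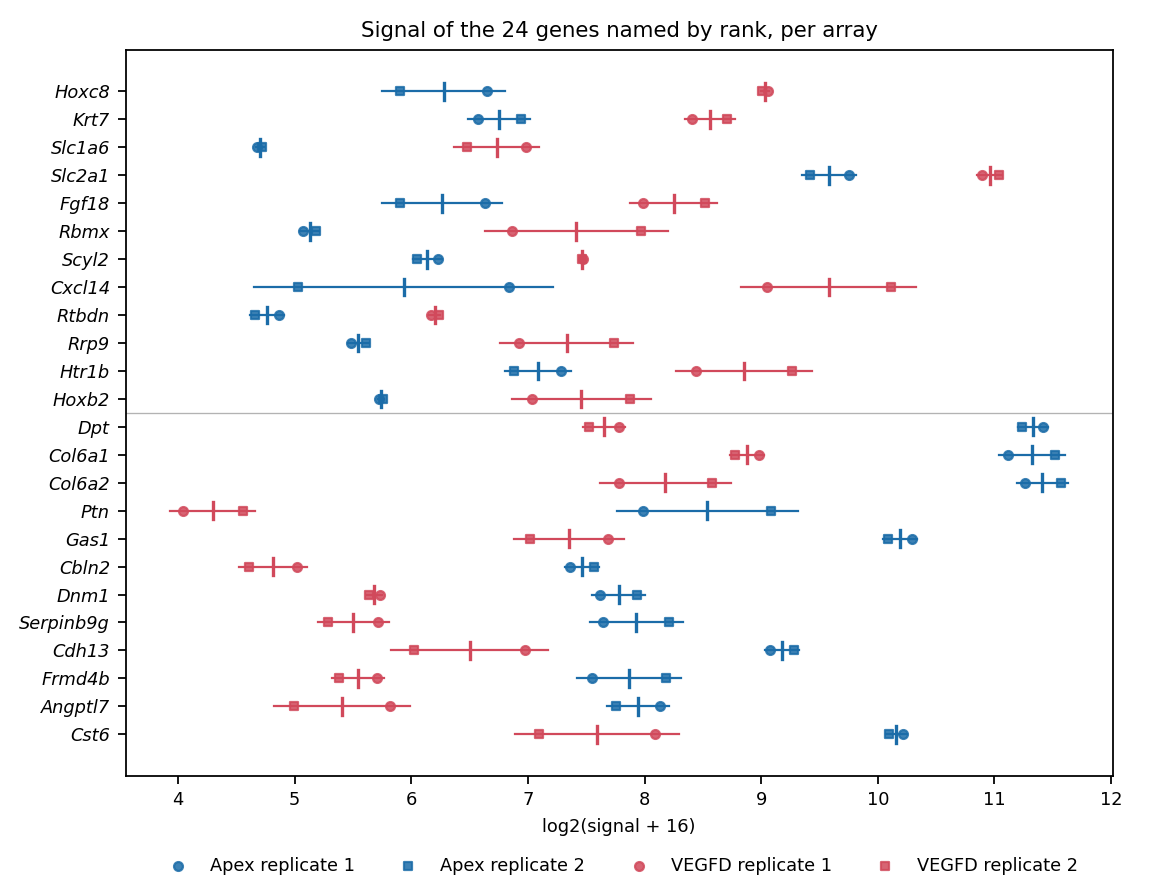
Signal as log2(signal + 16) on the horizontal axis for the 12 higher (top) and 12 lower (bottom) genes named by rank, with 1 point for each of the 4 arrays, a tick at the group mean and a line of 1 SD to each side (n = 2 a group). The groups do not overlap for these genes because the rule asked for that. None passed the main limma test, which had no block, and Dpt had the smallest adjusted p, 0.110.

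Among prostaglandin genes, Hpgd, which encodes the enzyme that inactivates prostaglandins, had signals of 281, 201, 82.9 and 13.3. Its log2 change was -2.24 ± 0.60 with an adjusted p of 0.825, and -1.47 with averaged probe sets. It was -1.36 without VEGFD replicate 2 (adjusted p = 0.319) and -3.12 without VEGFD replicate 1, where it passed (adjusted p = 0.00921). Ptgs2, which encodes the inducible cyclooxygenase COX-2, had signals of 387, 355, 466 and 2438, and a log2 change of 1.49 ± 0.75, which was 0.32 without VEGFD replicate 2 and 2.67, with an adjusted p of 0.00678, without VEGFD replicate 1. Ptgis, which encodes prostacyclin synthase, had 1.64 ± 0.63, which was 0.85 without Apex replicate 2. Ptges, the gene of an inducible prostaglandin E synthase, had -0.34 ± 0.28, which was -0.17 without Apex replicate 2, -0.22 with arrays centred on their medians and -0.89 with averaged probe sets. Of the 11 tested genes of prostaglandin synthesis, breakdown and transport, 5 were higher and 6 lower and 0 passed, also when adjusted over the list alone. The list had a median of -0.28, a mean of 0.0032, a camera direction of down and an adjusted p of 0.892. With 1 array left out its median ran from -0.30 to 0.26, and among those fits camera gave down only without VEGFD replicate 2. Of 5 tested prostanoid receptor genes 1 was higher and 4 lower (adjusted p = 0.758), with Tbxa2r, the thromboxane receptor gene, at -0.56 ± 0.66 and Ptgfr, the prostaglandin F receptor gene, at -0.55 ± 0.54. Without VEGFD replicate 2 the Tbxa2r value was 0.44, and without Apex replicate 2 the Ptgfr value was 0.21. With a pseudocount of 64 they were -0.32 and -0.31.

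The receptors for VEGF-D showed no call in either direction. Flt4, which encodes VEGFR-3, had signals of 42.6, 247, 161 and 145 and a log2 change of 0.45 ± 0.70, which was -0.64 without Apex replicate 1, 0.27 with averaged probe sets and 0.25 with a pseudocount of 64. Kdr, which encodes VEGFR-2, had -0.095 ± 0.30, and 0.028 with arrays centred on their medians, and the co-receptor gene Nrp2 had -0.93 ± 0.43, which was -0.35 without VEGFD replicate 1 and -1.51 without VEGFD replicate 2. The mouse Vegfd gene itself had signals of 4103, 3694, 4135 and 726, a log2 change of -1.16 ± 0.78 that was 0.086 without VEGFD replicate 2 and -2.40, with an adjusted p of 0.00921, without VEGFD replicate 1. Pgf, the placental growth factor gene, had 1.43 ± 0.38, which was 0.73 with a pseudocount of 64 and 2.16 with a pseudocount of 1, with Apex signals of 25.9 and 8.18. Of 11 tested VEGF ligand and receptor genes, 6 were higher, 5 lower and 0 passed, and the list had a camera adjusted p of 0.675.

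Genes of fat cells formed the single list that shifted. All 5 tested adipocyte markers had less signal in VEGFD arrays without overlap, and the list fell by camera with a median log2 change of -1.24 and an adjusted p of 0.00189. With an estimated correlation the adjusted p was 0.919, and by fry it was 0.475 (unadjusted p = 0.0528). Fry gave no list a lower adjusted p, and it too judges lists by the few arrays. Neither value therefore shows the camera call to be false. Adipoq, which encodes the fat cell hormone adiponectin, had signals of 38.3, 145, 12.7 and 12.5 and a log2 change of -1.71 ± 0.55. Fabp4, a fatty acid carrier gene that endothelial cells and macrophages also express, had 1741, 4073, 1098 and 1047 and a log2 change of -1.30 ± 0.42. Without Apex replicate 2 these were -0.92 and -0.69, and Adipoq was -0.93 with a pseudocount of 64. Pparg, Slc2a4 and Lpl had -1.24, -0.96 and -0.80. Over all genes 0 of the 5 passed, and 3 (Adipoq, Fabp4 and Lpl) passed adjusted over the list alone. The list was lower in each analysis with 1 array left out, with adjusted p from 7.6e-05 to 0.0178, or adjusted p = 0.892 to 0.984 with an estimated correlation. Too few of its members (3 and 4) were tested with a stricter filter or with averaged probe sets to run camera. In 4 of these genes the highest signal was in Apex replicate 2, the array that also had the highest endothelial signals.

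Pan-endothelial markers had less signal in VEGFD arrays for 10 of 10 tested genes, with a median log2 change of -0.61, and the list did not pass (adjusted p = 0.220). The difference rested on Apex replicate 2: the adjusted p was 1.5e-05 without Apex replicate 1 and 0.885 without Apex replicate 2. With an estimated correlation it was adjusted p = 0.892 without Apex replicate 1 and 0.919 on all 4 arrays. Emcn, which encodes the endothelial surface protein endomucin, had signals of 48.4, 2670, 106 and 23.97, and Egfl7, a gene of a protein secreted by endothelium, had 44.5, 216, 35.9 and 56.8. Their log2 changes were -2.58 ± 1.73 and -0.95 ± 0.66, and 0.12 and 0.022 without Apex replicate 2. Pecam1, which encodes CD31, had signals of 2.92, 141, 3.25 and 2.22 and lay below the filter. Blood endothelial markers had 2 of 8 genes higher and 6 lower (adjusted p = 0.758, and 0.0376 without Apex replicate 1, or adjusted p = 0.892 with an estimated correlation). They included Cd34, which encodes a surface sialomucin, at -2.05 ± 0.40 and Selp, which encodes P-selectin, at -1.87 ± 1.07, and -0.20 without Apex replicate 2. Cd34 was the 1 member that passed adjusted over the list alone, and without VEGFD replicate 1 it passed over all genes (-2.39, adjusted p = 0.0246).

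Of 10 tested lymphatic endothelial markers, 4 were higher and 6 lower, 0 passed over all genes, 2 passed adjusted over the list alone (Fgl2 and Maf), and the list had a camera adjusted p of 0.758. Prox1, the master transcription factor gene of lymphatic identity, had signals of 11.2, 11.6, 3.19 and 5.94 and lay below the filter. Pdpn, which encodes podoplanin, had signals of 963, 1622, 1237 and 1715 and a log2 change of 0.22 ± 0.33, which was -0.15 without Apex replicate 1, -0.015 without VEGFD replicate 2 and 0.34 with arrays centred on their medians. Lyve1, which encodes a hyaluronan receptor, had 16.5, 151, 22.0 and 14.5, a log2 change of -1.12 ± 0.77 that was 0.067 without Apex replicate 2, -1.77 with averaged probe sets and -0.68 with a pseudocount of 64. Fgl2 had the largest value of the list, 2.31 ± 0.57, and 2.78 without VEGFD replicate 1, where it passed (adjusted p = 0.0477). Stab1, the gene of the scavenger receptor stabilin-1, had -2.02 ± 1.13 with signals of 16.5, 348, 3.30 and 21.4, and -0.27 without Apex replicate 2 or -1.26 with a pseudocount of 64. Collecting vessel and valve genes had 3 of 15 higher and 12 lower (adjusted p = 0.651), with Itga5, an integrin gene, at 1.18 ± 0.81 and -0.095 without VEGFD replicate 2, and Sema3a, a guidance gene, at -0.69 ± 0.47 and -0.028 without Apex replicate 2. With averaged probe sets these were 0.66 and -0.42, and without VEGFD replicate 1 Itga5 was 2.46 and passed (adjusted p = 0.00921).

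Markers of other cells that dissected vessels can carry were measured on all arrays. Smooth muscle and pericyte markers were higher for 7 of 11 genes (adjusted p = 0.758), led by the contractile genes Tagln (2.34 ± 0.61; signals of 454, 746, 1632 and 5553) and Myl9 (1.97 ± 0.67), which were 1.46 and 1.03 without VEGFD replicate 2, and 3.22 and 2.91 without VEGFD replicate 1, where both passed (adjusted p = 0.00874 and 0.0133). Fibroblast markers were higher for 6 of 11 genes (median 0.046, mean -0.18, direction up by camera, adjusted p = 0.832), with Dpt alone passing adjusted over the list alone and Mfap5, a microfibril gene, at 0.84 ± 0.31 and 0.43 without Apex replicate 2. Epithelial and keratinocyte markers were lower for 6 of 7 genes (median -0.85, camera adjusted p = 0.125). With 1 array left out the median ran from -0.95 to -0.40. Dsp, which encodes the junction protein desmoplakin, was the 1 member that passed adjusted over the list alone, at -2.24 ± 0.52. Dsp was -1.42 with a pseudocount of 64 and passed over all genes without VEGFD replicate 1 (-2.98, adjusted p = 0.00921). With arrays centred on their medians this list passed, at an adjusted p of 0.0428, and without Apex replicate 1 it passed at 0.0376. With an estimated correlation these were adjusted p = 0.932 and 0.892. Perp, the second gene named from it, had -0.96 ± 0.71, 0.11 without VEGFD replicate 2 and -2.02 without VEGFD replicate 1 (adjusted p = 0.0250). The nerve and glial list had 4 of 6 genes lower (adjusted p = 0.758), with S100b at -1.23 ± 0.55, and -0.61 without VEGFD replicate 2, and Mbp, whose probe sets differed in sign, at 0.40 ± 0.50. With a pseudocount of 64 these were -0.81 and 0.25, and Mbp was -0.58 with averaged probe sets.

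Muscle and immune cell lists gave no call. Skeletal muscle markers had 2 of 5 genes higher (median -0.23, mean 0.23, direction up by camera, adjusted p = 0.832), with Acta1 at 1.34 ± 1.003, -0.17 without VEGFD replicate 2 and 2.84 without VEGFD replicate 1 (adjusted p = 0.0239), and Mylpf at 0.53 ± 0.30, and 0.35 without VEGFD replicate 1. Macrophage markers had 2 of 5 higher (median -0.064, mean 0.025, direction up by camera, adjusted p = 0.832), with Cd68 at 0.24 ± 0.32 and Adgre1 at 0.23 ± 0.32, which were -0.0081 and -0.049 without Apex replicate 2. Lymphocyte markers, with 3 tested genes (median 0.031, mean -0.036), and granulocyte and mast cell markers, with 4, were too few for camera. In these, Cd8a had -0.32 ± 0.32, Ighm 0.18 ± 0.32 with probe sets of opposite sign, S100a8, a neutrophil protein gene, -1.68 ± 0.59 and Cma1, a mast cell protease gene, -0.51 ± 0.29. Without Apex replicate 1, Cd8a was -0.074 and Cma1 -0.31, and without VEGFD replicate 2 S100a8 was -0.79. Without VEGFD replicate 1 S100a8 passed (-2.57, adjusted p = 0.00857). With a pseudocount of 64 the values were 0.26 for Mylpf, 0.13 for Cd68, 0.10 for Adgre1, -0.18 for Cd8a, 0.12 for Ighm and -0.27 for Cma1. With a pseudocount of 1 Mylpf was 0.81 and Adgre1 0.39. With arrays centred on their medians Cd68 and Adgre1 were both 0.36, Ighm 0.30 and Cd8a -0.19, and with averaged probe sets Cd8a was -0.11 and Ighm -0.017.

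**Figure D2:**
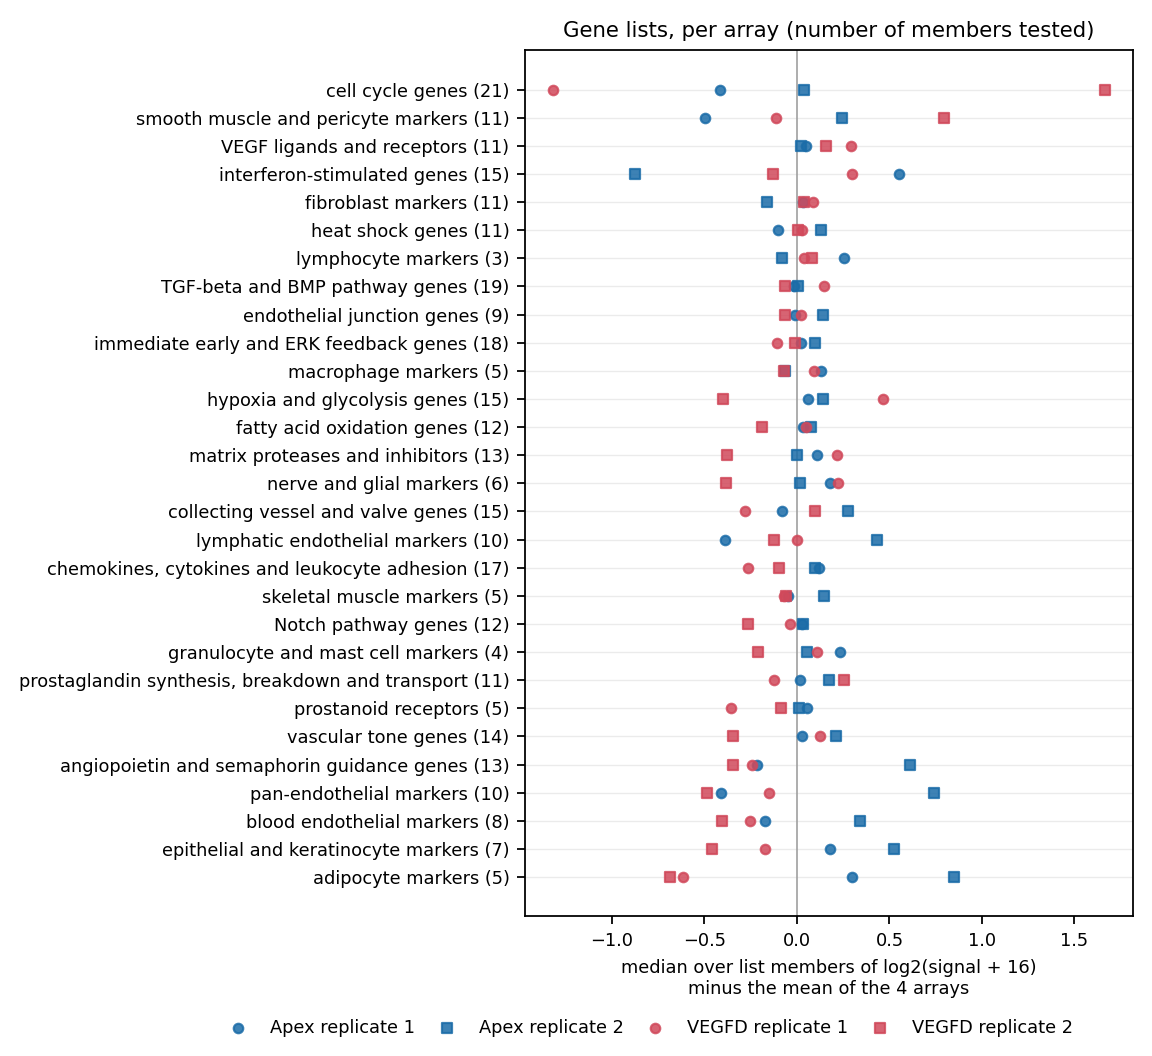
Median over the tested members of each gene list of log2(signal + 16) minus each gene's mean over the 4 arrays, with 1 point per array and the number of members tested beside the list name. The adipocyte markers had both VEGFD arrays (-0.62 and -0.68) below both Apex arrays (0.30 and 0.85), and the cell cycle genes had the VEGFD arrays at opposite ends (-1.32 and 1.67).

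Cell cycle genes were higher for 18 of 21 genes, with a median log2 change of 0.37 and an adjusted p of 0.505, and the 2 VEGFD arrays lay at opposite ends. Cdc20, a mitotic exit gene, had signals of 246, 478, 125 and 2282 and a log2 change of 0.66 ± 1.28. Mcm6, a DNA replication gene, had 0.79 ± 0.66, and 0.24 with averaged probe sets. Camera called the list up without VEGFD replicate 1 (adjusted p = 5.4e-18) and down without VEGFD replicate 2 (adjusted p = 9.6e-14), where Cdc20 was -1.35 and Mcm6 -0.14. Both calls assume the preset correlation of 0.01, while the estimate for this list was 0.836 on all 4 arrays (adjusted p = 0.919). Without VEGFD replicate 1 Cdc20 passed at 2.67 (adjusted p = 0.0177). Hypoxia and glycolysis genes were lower for 10 of 15 (median -0.072, mean -0.18, direction up by camera, adjusted p = 0.889). That list was called down without VEGFD replicate 1 (adjusted p = 0.0178) and up without VEGFD replicate 2 (adjusted p = 0.00142). With an estimated correlation these were adjusted p = 0.984 and 0.927. Slc2a1 was the gene of this list that passed adjusted over the list alone. Pdk1 had -1.53 ± 0.80 and Ndrg1 -1.46 ± 1.07, both with the lowest signal in VEGFD replicate 2, and without that array Pdk1 was -0.30 and Ndrg1 0.25. Without VEGFD replicate 1 both passed, at -2.75 and -3.16 (adjusted p = 0.00921 and 0.00552), and with averaged probe sets Pdk1 was -0.85.

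Interferon-stimulated genes were higher for 9 of 15 (adjusted p = 0.536), and the list was called up without Apex replicate 1 (adjusted p = 5.5e-06) and down without Apex replicate 2 (adjusted p = 0.0409). With an estimated correlation these were adjusted p = 0.892 and 0.971, and on all 4 arrays it was adjusted p = 0.919 at a correlation of 0.641. Oasl2 had signals of 363, 40.3, 352 and 243 and Oas1a had 492, 83.4, 427 and 428. Their log2 changes of 1.08 ± 0.88 and 0.98 ± 0.75 were -0.30 and -0.19 without Apex replicate 2. Among chemokines, cytokines and leukocyte adhesion genes, 12 of 17 were lower (adjusted p = 0.536), with the chemokine gene Ccl7 at -1.57 ± 0.47, and -0.94 without Apex replicate 2, and the cytokine gene Il6 at 1.37 ± 0.37. Immediate early and ERK feedback genes had 8 of 18 higher (adjusted p = 0.892), with Dusp5 at 1.53 ± 1.16, and Spry4 at -1.11 ± 0.37. Dusp5 was -0.29 without VEGFD replicate 2 and 3.34 without VEGFD replicate 1, where it passed (adjusted p = 0.00921). Spry4 was -0.71 without Apex replicate 2 and -0.50 with averaged probe sets. Heat shock genes had 6 of 11 higher (median 0.032, mean -0.13, direction down by camera, adjusted p = 0.892), with Hspa1b at -1.22 ± 0.33 and Hspa1a at -0.68 ± 0.34, -0.34 without Apex replicate 2 and -0.40 with a pseudocount of 64.

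Lists of vessel signalling and matrix turnover gave no call on all 4 arrays. Angiopoietin and semaphorin guidance genes were lower for 10 of 13 (adjusted p = 0.505, and 0.0138 without Apex replicate 1, or adjusted p = 0.892 with an estimated correlation). Those tested included Angpt1, a ligand gene of the Tie2 receptor, at -1.11 ± 0.30 and Sema3f at -0.97 ± 0.27. With averaged probe sets these were -0.59 and -0.37, and with a pseudocount of 64 they were -0.70 and -0.54. Vascular tone genes were lower for 10 of 14 (adjusted p = 0.569), with Ramp2, a co-receptor gene for adrenomedullin, at -1.71 ± 0.42, and -1.09 with a pseudocount of 64. Notch pathway genes were lower for 8 of 12 (adjusted p = 0.758), with Notch3 at -1.17 ± 0.42, and -0.77 without VEGFD replicate 2, and Nrarp at -1.12 ± 0.78, 0.087 without Apex replicate 2 and -0.73 with a pseudocount of 64. TGF-beta and BMP pathway genes were higher for 9 of 19 (median -0.040, mean -0.0050, direction up by camera, adjusted p = 0.826), with the receptor genes Tgfbr1 at 1.37 ± 0.42 and Acvrl1 at 1.19 ± 0.70. Acvrl1 was 0.14 without Apex replicate 2 and 2.24 without Apex replicate 1. Endothelial junction genes were lower for 6 of 9 (adjusted p = 0.826), with Esam at -0.93 ± 0.75, 0.21 without Apex replicate 2 and -0.60 with a pseudocount of 64, and Jam2 at 0.88 ± 0.31, and 0.55 without VEGFD replicate 2. Matrix proteases and inhibitors were lower for 7 of 13 (adjusted p = 0.826), with the inhibitor gene Timp4 at -1.999 ± 0.298, which passed adjusted over the list alone, and the urokinase receptor gene Plaur at 1.31 ± 0.70. Timp4 was -1.31 with averaged probe sets, -1.11 with a pseudocount of 64 and -2.16 without VEGFD replicate 1, where it passed over all genes (adjusted p = 0.0294). Plaur was 0.22 without VEGFD replicate 2 and 2.40 without VEGFD replicate 1, where it passed (adjusted p = 0.00921). Fatty acid oxidation genes were lower for 10 of 12 (adjusted p = 0.505), with Pdk4 at -1.28 ± 0.97, 0.25 without VEGFD replicate 2 and -2.82 without VEGFD replicate 1 (adjusted p = 0.00874), and Slc25a20 at -0.55 ± 0.31, and -0.19 without Apex replicate 2.

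The arrays differed in ways that did not follow the groups. The correlation of log2 signals over tested genes was 0.970 between Apex replicate 1 and VEGFD replicate 1, above the 0.956 between the Apex arrays and the 0.918 between the VEGFD arrays. Apex replicate 2 carried signals of Y-linked genes, with Eif2s3y at 649 and Uty at 162, and had Xist, the gene of the X-inactivation RNA, at 20.1. In the other 3 arrays Eif2s3y lay between 1.53 and 6.36 and Xist between 876 and 1679. The 3' minus 5' difference of the Gapdh and Actb control probe sets, a sign of RNA integrity, was 0.11 and 0.34 on the log2 scale in the Apex arrays and 0.060 and -0.028 in the VEGFD arrays. Between Apex replicate 1 and VEGFD replicate 1 alone, a comparison chosen after the data were seen, 374 genes were 2-fold apart. Of these, 169 were among the 446. Their shared direction was fixed in advance, because the 446 had no overlap and include these arrays.

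**Figure D3:**
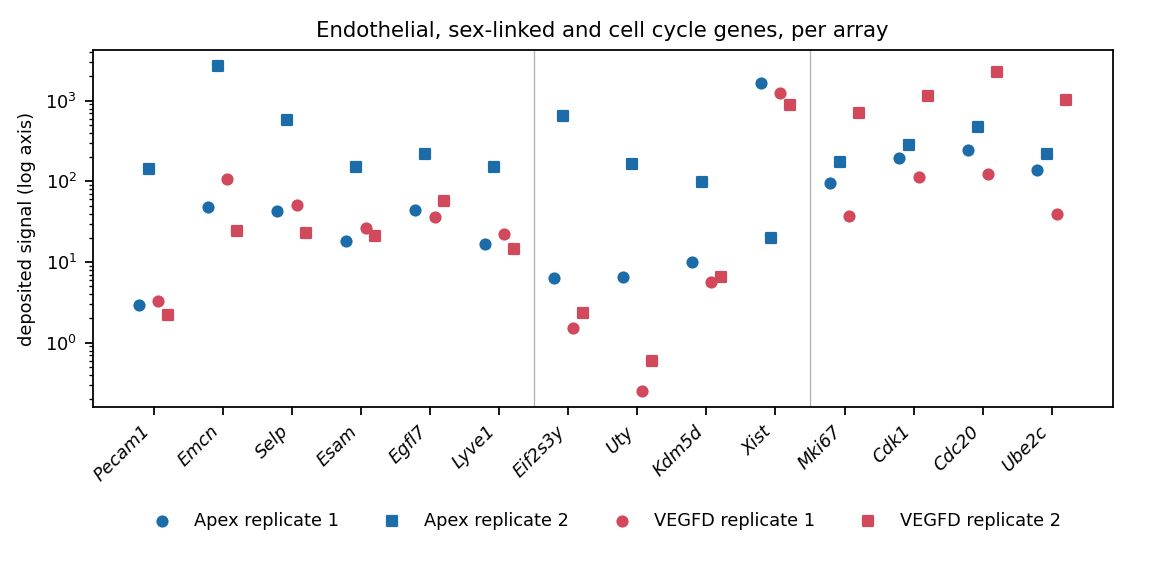
Deposited signal on a log axis, 1 point per array, for endothelial markers (left), sex-linked genes (middle) and cell cycle genes (right), chosen after the values were seen. Apex replicate 2 had the highest endothelial and Y-linked signals (Pecam1 at 141, Eif2s3y at 649) and VEGFD replicate 2 the highest cell cycle signals (Cdc20 at 2282).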

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

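Alternatives without the arrays that stand apart, without Y-linked genes and Xist, without the cell cycle and endothelial lists, and with an estimated correlation on 3 arrays were chosen after seeing the data. In limma with all 4 arrays, 0 genes passed under each scaling, filter, probe set rule, variance model and pseudocount tried, with either gene exclusion, and at an adjusted p of 0.1; 666 lay at an unadjusted p under 0.05. At an unadjusted p under 0.01 there were 135 genes, 38 higher and 97 lower, where 117 would arise by chance. The split by replicate number gave 114 and the remaining split 8. With the replicate number as a block, 6 genes passed, 0 higher and 6 lower (Dpt, Ptn, Col6a2, Gas1, and, chosen after their values were seen, Tgfbi and Mgp). The labels do not say whether same-numbered arrays pair, and their deviations correlated at 0.20. With 1 array left out, 0 to 390 genes passed (higher 0 to 146, lower 0 to 244), 436 to 1329 were 2-fold apart without overlap and 2 to 6 lists shifted. Of the 390 genes, 195 were among the 446 and 13 were on the fixed cell cycle list of 21 tested genes, with cell cycle genes outside it not counted; the 4 called without VEGFD replicate 2 were Dpt, Col6a2 and, chosen after their values were seen, Col6a3 and Dkk2. The cause was not tested. The 446 became 225 with the filter at the 75th percentile and 804 with every probe set counted, where fewer or more features were tested. The count was 228 with a pseudocount of 64, which shrinks dim genes, and 304 to 608 in the other alternatives with all 4 arrays. Counts with arrays left out are not comparable with the 446, since no overlap is easier to meet with fewer arrays. Lists shifted numbered 2 with median centring and with every probe set (epithelial added), and 0 with the 75th percentile filter or averaged probe sets (too few adipocyte genes tested), an estimated correlation (on all 4 arrays or with 1 left out) or fry. Of 89 named genes, 27 reversed sign somewhere, and 40 passed somewhere, each of these 40 without VEGFD replicate 1, 4 with the block and 2 without VEGFD replicate 2. Changes of over 1.5 times were met by 53 of the named genes with 1 array left out, 33 with a pseudocount of 64, 22 with averaged probe sets, 8 with a pseudocount of 1 and 7 with another scaling. Recomputed list medians moved by more than the spread between replicates in 98 cases and by less in 449. Averaged probe sets gave Ighm -0.017 and Mbp -0.58, and median centring gave Kdr 0.028. Without Apex replicate 2 and VEGFD replicate 2, log2 values were Tbxa2r 0.27, Ptgfr 0.13, Vegfd 0.011, Emcn 0.92, Selp 0.19, Adgre1 -0.075, Ighm -0.16, Perp 0.41, Mcm6 -0.53, Cdc20 -0.90, Esam 0.32, Oasl2 -0.041, Oas1a -0.20, Ndrg1 0.078, Nrarp 0.24, Kdr 0.17, Lyve1 0.23 and Pecam1 0.025. With 1 array left out the values ran for Tbxa2r from -1.56 to 0.44, Ptgfr -1.31 to 0.21, Vegfd -2.40 to 0.086, Itga5 -0.095 to 2.46, Emcn -5.27 to 0.12, Egfl7 -1.92 to 0.022, Acta1 -0.17 to 2.84, Cd68 -0.0081 to 0.48, Adgre1 -0.049 to 0.51, Ighm -0.17 to 0.52, Perp -2.02 to 0.11, Mbp -0.14 to 0.93, Mcm6 -0.14 to 1.72, Cdc20 -1.35 to 2.67, Dusp5 -0.29 to 3.34, Esam -2.08 to 0.21, Oasl2 -0.30 to 2.45, Oas1a -0.19 to 2.16, Ndrg1 -3.16 to 0.25, Pdk4 -2.82 to 0.25, Nrarp -2.32 to 0.087, Flt4 -0.64 to 1.53, Kdr -0.39 to 0.20, Pdpn -0.15 to 0.59, Lyve1 -2.30 to 0.067, Nrp2 -1.51 to -0.35, Stab1 -3.76 to -0.27, Selp -3.53 to -0.20, Sema3a -1.35 to -0.028, Acvrl1 0.14 to 2.24, S100b -1.85 to -0.61, Cd8a -0.56 to -0.074, Hspa1a -1.02 to -0.34, Slc25a20 -0.90 to -0.19, Ptges -0.51 to -0.17 and Pecam1 -3.07 to -0.015. Genes near the signal of the filter have log2 changes compressed by the pseudocount.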

Other observations

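The tests below were chosen after the pattern was seen, except the test of limb-level genes, which was written before its result. Of 25 tested collagen genes, a group chosen after the values were seen, 16 were lower and 9 higher in VEGFD arrays, with a median log2 change of -0.073. The collagen VI chains stood at the lower end, with Col6a1 at -2.44, Col6a2 at -3.23 and Col6a3 at -2.61, each without overlap between groups. None passed limma's adjusted threshold on 4 arrays without a block. With the replicate number as a block Col6a2 passed (adjusted p = 0.022). The Col6a3 value rested on VEGFD replicate 1 and was -0.78 without it, and -4.43 without VEGFD replicate 2 (adjusted p = 0.0128). Without VEGFD replicate 1 Col6a1 and Col6a2 passed (adjusted p = 0.00921 and 0.00816), and without VEGFD replicate 2 Col6a2 passed (0.0128). Col5a2, a chain of collagen V, was at 0.87.

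Hox genes, which record position along the body axis, differed by paralogue number and by cluster, a pattern noticed in these values. Of 11 tested genes of paralogue groups up to 8, 9 were higher in VEGFD arrays, with Hoxc8 at 2.75, Hoxb6 at 1.57 and Hoxc4 at 1.54 and a mean log2 change of 1.04 ± 0.96 (SD over genes). The exceptions were Hoxa3 at -0.50 and Hoxa5 at -0.38. Of 7 genes of groups 9 and above, 6 were lower, with Hoxd9 at -1.30 and Hoxa11 at -1.21 and a mean of -0.82 ± 0.70, and Hoxc9 was higher at 0.73. The means differed by 1.87, and no p is given for a difference seen and measured on the same genes. By cluster, 5 of 5 Hoxa genes were lower and 4 of 4 Hoxb genes higher, 5 of 7 Hoxc genes were higher, and 1 of 2 Hoxd genes was. None of the 18 genes passed limma's adjusted threshold on 4 arrays, and 6 did without VEGFD replicate 1, namely Hoxc8 (adjusted p = 0.0168), Hoxb2 (0.0218), Hoxd9 (0.0324), Hoxb6 (0.0362), Hoxb3 (0.0383) and Hoxc4 (0.0416). Hoxd9 was -2.12 there and -0.47 without VEGFD replicate 2, and Hoxb6 was 1.03 without VEGFD replicate 2. Hoxa3 was -0.059 without VEGFD replicate 1 and -0.95 without VEGFD replicate 2, and Hoxa5 was -0.018 without Apex replicate 2 and -0.74 without Apex replicate 1. With 1 array left out the difference of the means ran from 1.71 to 2.02. The mean of groups 9 and above was -0.53 without VEGFD replicate 1 and -1.12 without VEGFD replicate 2. Without VEGFD replicate 1 Hoxa9 was -0.11 and Hoxa10 -0.36, against -0.98 and -1.07 on all 4 arrays.

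The Hox pattern may come from vessels taken at different body levels in the groups. A single deviating array is argued against, since the difference exceeded 0.5 in 4 of the 4 pairs of an Apex and a VEGFD array (1.62 to 2.11), against 0.18 between the Apex arrays and -0.32 between the VEGFD arrays. Outside the Hox clusters, the hindlimb-level genes Pitx1 and Tbx4 were lower, as a different level would have it. Pitx1 was at -1.29 ± 0.44 (SE, limma adjusted p = 0.825), and -0.73 without VEGFD replicate 1, and Tbx4 was at -0.66. The forelimb-level gene Tbx5 was at -0.31 ± 0.45, but 0.20 without Apex replicate 1 and 0.041 without VEGFD replicate 2. Its direction was therefore not settled. The rule written beforehand asked for Tbx5 minus the mean of the others to be positive by more than 2 of its SEs. It was 0.67 ± 0.51, and 0.0082 to 1.33 with 1 array left out, so the rule was not met. Tbx5 and Tbx4 lay below the filter. A different body level and a biological difference by VEGF-D therefore cannot be told apart. The site of dissection on each mouse is not known here.

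Endothelial markers were highest in Apex replicate 2 for 81.25% of the 16 pan-endothelial genes on the array, where 95% of random lists matched on signal had at most 56.25%. List and array were paired after the values were seen, and the tested members vary together (estimated correlation 0.535). The random lists are therefore no test of that share and describe only genes of like signal. A candidate explanation is a larger share of endothelial RNA in that array, and it does not follow the groups, since Apex replicate 1 lay with the VEGFD arrays. A shift shared by all genes of like signal is argued against, because the list median was 1.34 above the mean of the other 3 arrays on the log2 scale and 95% of matched random lists had at most 0.35. Other lists gave a mixed picture of a larger endothelial share. Of the lymphatic markers 57.14% were highest there, equal to the bound of 57.14%, while their list median of 0.58 exceeded its bound of 0.32. Prox1 was at most 14.6 on any array. Few fibroblast markers were highest there (21.43%, list median -0.19, where 0.64% of random lists were lower), although Col1a2 was. The blood endothelial markers (42.86%, a random median of 35.71%, list median 0.20) lay inside their random range, although Selp stood at 578 there and at most 51.0 elsewhere. The sex of the mouse and this array cannot be told apart, because 1 array had male-type signals, and a mouse or label from outside the stated design was not tested.

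Cell cycle genes were highest in VEGFD replicate 2 for 95.45% of 22 genes, where 95% of random lists matched on signal had at most 50.0%. Here too list and array were paired after the values were seen, and the tested members vary together (estimated correlation 0.836). The random lists are therefore no test of that share. More cycling cells in VEGFD replicate 2 may account for the high share, a hypothesis from the same data. A shift shared by all genes of like signal (list median 2.20, where 95% of matched random lists had at most 0.18) and RNA degradation (a 3' minus 5' difference of -0.028, below the highest of the other arrays, 0.34) are argued against. VEGFD replicate 1 had the lowest cell cycle median, -1.32, so the level did not follow the groups.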
